A study of Homo sapiens with 4 samples.

How the data were processed

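Gene expression was measured by stranded mRNA sequencing of 143B cells, a human osteosarcoma line, 2 days after lipid-based transfection of siRNA. Per the labels, 2 libraries came from cells given a non-targeting siRNA (siNC) and 2 from cells given siRNA against CBX3 (siCBX3), and sequencing was on a NovaSeq instrument. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.3a and featureCounts of Subread 1.5.1, with genome build GRCh38. The roles of the tools, their settings for strand and shared reads, the annotation release and any use of molecular identifiers were not given in the sources used here. The number and sequences of the siRNAs were not given either. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

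The authors deposited a table of raw read counts per gene and a table of RPKM values, each with the same 37450 features, and per the file headers each column holds 1 library. The deposited RPKM values equal the counts scaled by gene length and library total to a relative difference of at most 3.8e-07. Total counts were 37318382 and 40336907 in siNC and 36509298 and 38717507 in siCBX3. Coordinates are those of the count table. Biotypes, 3' UTRs and transcript sequences came from GENCODE 29, and matched features held 99.56% of reads.

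Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 20999, and libraries were scaled with TMM factors. A quasi-likelihood model with group as its only term was fitted to all 4 libraries, with 2 residual degrees of freedom and 22.0 prior ones. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, with no limit on fold change. Levels are TMM-scaled CPM, as mean ± SD over the 2 libraries of a group. Log2 fold changes are siCBX3 minus siNC from the edgeR fit at its default prior count. Their standard errors (SE) are the size of the log2 fold change over the root of the F statistic. A prior count of 2 was used for log2 CPM values. Precision figures cover counting error and the spread of these libraries, and reads without molecular identifiers are not independent molecules.

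The genes named were fixed by a rule before the data were examined. The rule took CBX3, the 12 largest and 12 smallest log2 fold changes and the 5 smallest p-values among changed coding genes with at least 100 counts in the higher group and no overlap between groups. It also took up to 4 members of each gene list with the smallest adjusted p, and the measured neighbours of CBX3. Not every gene the rule took is reported here. A total of 38 gene lists was fixed at the same time. These covered heterochromatin and polycomb proteins, CBX3 neighbours, zinc finger genes (all, and those on chromosome 19), PCDHB, HOX and germline genes, and cell cycle, p53, interferon, NF-kB, apoptosis, stress and metabolic genes. They also covered ribosomes, matrix, adhesion, signalling targets, the osteoblast lineage, splicing, DNA repair, histones, RNA interference, and epithelial, leukocyte and endothelial markers. Each list was tested on log2 CPM with limma 3.58.1, by camera at a preset correlation of 0.01, by camera with an estimated correlation, and by fry, with adjustment over the lists. Counts of called members are given by adjustment over all genes and adjusted over the list alone.

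Genes that share exon bases were examined after the data had been seen. Among 77 genes with at least 90% of their exon bases under a gene on the opposite strand, fold changes followed those of the covering gene across 73 pairs (Spearman 0.926 across genes, against a mean of -0.0105 after shuffling). The 12 PCDHGA genes, whose last exons are in common, had total counts between 2240 and 2276. The counts were therefore treated as not separating strands or overlapping genes, and 47.1% of tested genes share exon bases with another tested gene. Antisense, overlapping and near-identical genes are treated as uncertain.

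A scan of 3' UTRs for 7-mers was also added after the data had been seen. It regressed the log2 fold changes of 12013 coding genes on the presence of each of 16384 7-mers in the longest annotated 3' UTR, after removing trends with UTR length, UTR and gene GC content and gene length. It was repeated on 100 shuffles. Scans and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

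The steps were tested on simulated data. With 200 of 20560 genes changed at 2 libraries per group, the edgeR step recovered 11 of 50 genes changed 1.25-fold, 38 of 50 changed 1.5-fold, 45 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 5 unchanged genes among 149 calls. A raised and a lowered list were both called, and an unchanged list was not (adjusted p 0.406). The 7-mer scan ranked the planted 7-mer first in 5 of 5 draws at a shift of -0.4, in 4 of 5 at -0.2, in 0 of 5 at -0.1 and in 0 of 5 with no shift. The count of shared exon bases was checked on gene models with known overlaps.

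Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, upper-quartile scaling and library totals in place of TMM. Tests with DESeq2 and limma-voom, no low-count filter, a mean of at least 50 counts, coding genes alone, a replicate block and the omission of each library in turn were also run. The deposited RPKM values were tested with limma after adding 1 or 0.1, and thresholds of 0.01, of an absolute log2 fold change of 1 and of a 1.5-fold change by glmTreat were applied. Offsets for GC content and gene length, and results without genes that hold the 7-mer, were chosen after seeing the data. Reads, isoforms and genome-wide binding of the CBX3 protein were not analysed here.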

Results

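Messenger RNA was profiled in 143B osteosarcoma cells 2 days after transfection, in 2 libraries with non-targeting siRNA (siNC) and 2 with siRNA against CBX3 (siCBX3). CBX3 encodes HP1γ, a chromatin protein that binds methylated histone tails. Total counts were 37318382 and 40336907 in the siNC libraries and 36509298 and 38717507 in the siCBX3 libraries. Across genes, log2 CPM had a Pearson correlation of 0.991 within each group and between 0.957 and 0.961 across groups. The libraries of a group were not copies of 1 file (chi-square per degree of freedom 13.1 in siNC and 7.58 in siCBX3), which does not show whether they were separate cultures.

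The comparison asked how the transcriptome of 143B cells differed once CBX3 was depleted. CBX3 (chromosome 7, 26201162 to 26213356, plus strand, GRCh38) had 20311 and 21384 counts in siNC and 2020 and 2163 in siCBX3. Its level was 523 ± 22.2 CPM (SD, n = 2) in siNC and 57.2 ± 0.165 CPM in siCBX3, which was 9.15-fold lower. The log2 fold change was -3.19 (SE 0.08, adjusted p 2.73e-20, edgeR quasi-likelihood test). CBX3 shares 368 of its 4641 exon bases with HNRNPA2B1 on the opposite strand, an abundant gene, so the count that remained in siCBX3 can include HNRNPA2B1 reads. The other HP1 genes changed less, with log2 fold changes of -0.54 for CBX5 and -0.19 for CBX1 (adjusted p 0.0416, edgeR); both were chosen after their values were seen.

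Genes of the NF-kB and matrix lists were mostly higher with siCBX3, and genes of cell division, DNA replication, ribosome assembly and the YAP target list mostly lower. Camera called these lists at the preset correlation, but each had adjusted p = 0.604 with an estimated correlation. Fry called each of them (adjusted p 0.0109 to 0.0142). The test with an estimated correlation rests on the 2 residual degrees of freedom, which raises its p-values. It can still be passed: it called the raised and lowered lists of the simulation, whose genes were drawn independently (camera adjusted p 0.00883). In each list named above the estimated correlation was over the preset 0.01, from 0.032 (NF-kB) to 0.267 (matrix). The p-values at the preset correlation can therefore be too small. In the list of NRF2 and ferroptosis genes the estimated correlation was -0.0217, under the preset 0.01. Its unadjusted camera p still went from 0.000745 to 0.0646. The chemokine CXCL8 rose from 2.95 ± 0.339 to 188 ± 1.57 CPM (n = 2 per group), 64.0-fold. FN1, which encodes the matrix protein fibronectin, rose 17.0-fold from 242 ± 0.0981 to 4105 ± 114 CPM. The proliferation marker MKI67 fell from 3169 ± 218 to 1450.0 ± 37.9 CPM. Of 20999 genes tested, 10173 changed (adjusted p under 0.05, edgeR), 5132 higher and 5041 lower in siCBX3. The balance turned to 4243 higher and 5917 lower with library totals in place of TMM. Among 14582 coding genes 8144 changed. Of all changed genes 4751 share exon bases with another tested gene, so their counts can include its reads, and 5422 share none. Only 2696 genes changed with an absolute log2 fold change of at least 1.

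**Figure D1:**
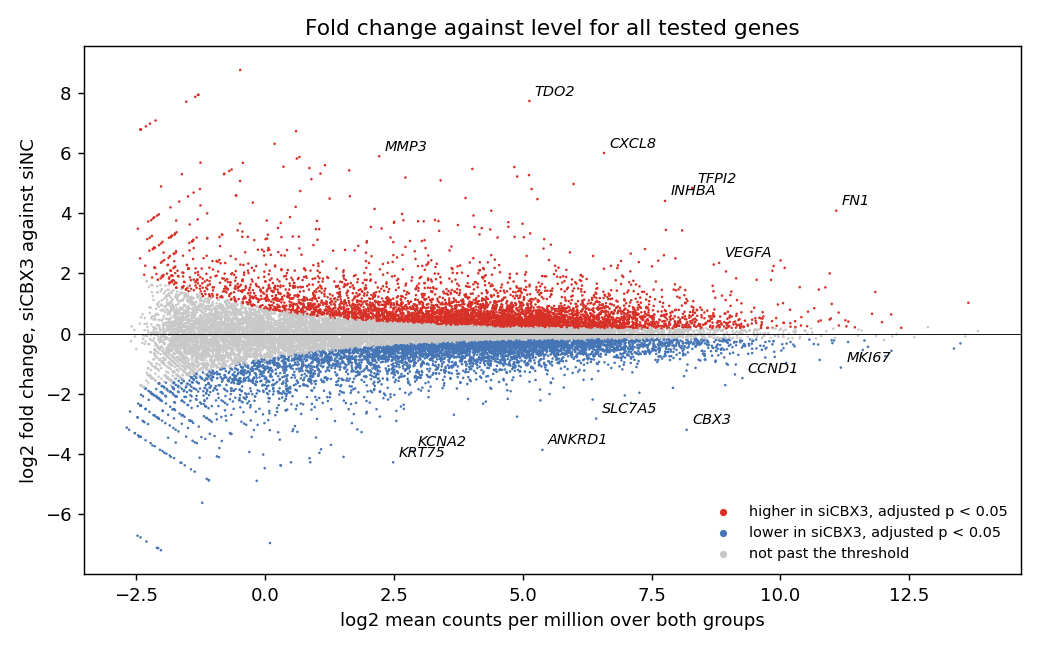
Each point is a tested gene, with log2 mean CPM over both groups on the x axis and the edgeR log2 fold change of siCBX3 against siNC on the y axis; red and blue mark genes with adjusted p under 0.05. The 5132 higher and 5041 lower genes spread over the whole range of levels, with TDO2, CXCL8 and FN1 far above 0 and CBX3 and ANKRD1 far below it.

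The 12 largest rises included genes of cytokines, enzymes and lectin receptors. TDO2, which starts the breakdown of tryptophan, rose from 0.323 to 69.7 CPM (log2 fold change 7.73, SE 0.16, adjusted p 6.45e-22, edgeR). The cytokine IL6 rose by 5.42 on the log2 scale, PTGS2, which makes prostaglandins, by 5.26, and the matrix protease MMP3 by 5.89. C8orf4 rose from 1.21 to 55.9 CPM. The genes with the smallest p-values were CXCL8 (adjusted p 1.14e-22, edgeR), TFPI2, INHBA, FN1 and TDO2. TFPI2, a secreted protease inhibitor, rose from 21.1 to 603 CPM, and INHBA, which encodes the activin A subunit, from 19.5 to 415 CPM. Several genes of this group, IL6 (7 and 4 counts) and MMP3 (8 and 4) among them, were near the detection limit in siNC, with single-digit counts per library. CSF2, which encodes the growth factor GM-CSF, had 0 and 4 counts in siNC and 111 and 108 in siCBX3, and TNIP3, an NF-kB inhibitor, 0 and 8 against 146 and 154. KLRC2, KLRK1, KLRC4-KLRK1 and RP11-277P12.6, from the lectin receptor cluster of chromosome 12, stood at 2.99 to 4.38 CPM in siCBX3 and at 0.0859 CPM or less in siNC. These 4 share exon bases with one another or with KLRC3, so their reads cannot be assigned to 1 gene.

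The genes with the largest falls included growth factors, receptors and differentiation genes. KRT75, a hair follicle keratin, fell from 10.6 to 0.546 CPM (log2 fold change -4.27, SE 0.23, adjusted p 1.17e-13, edgeR). ANKRD1, a target of the YAP coactivator, fell from 78.1 ± 7.27 to 5.36 ± 0.963 CPM and was the most abundant of the 12 in siNC. The receptor tyrosine kinase gene KIT had a log2 fold change of -3.96, the growth factor FGF9 -3.84 and the potassium channel gene KCNA2 -3.90. The activin subunit gene INHBB had -3.27, against the rise of INHBA. The cholesterol hydroxylase gene CYP46A1 (-4.27), the imprinted gene MEST (-4.14), HAP1 (-4.09), ADAM32 (-3.69) and the amino acid transporter gene SLC7A3 (-3.45) were below 6 CPM in siNC. KIT (3.89 CPM) and FGF9 (3.96 CPM) were below it too. Few counts were left in siCBX3, such as 10 and 4 for MEST and 10 and 8 for KIT, so the sizes are imprecise. The edgeR SE was 0.36 for MEST and 0.33 for KIT. Over the alternatives MEST lay between -4.98 and -0.756 and KIT between -4.22 and -0.714. These ranges include RPKM plus 1, where the added 1 shrinks the fold changes of such low genes, so they do not measure precision.

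**Figure D2:**
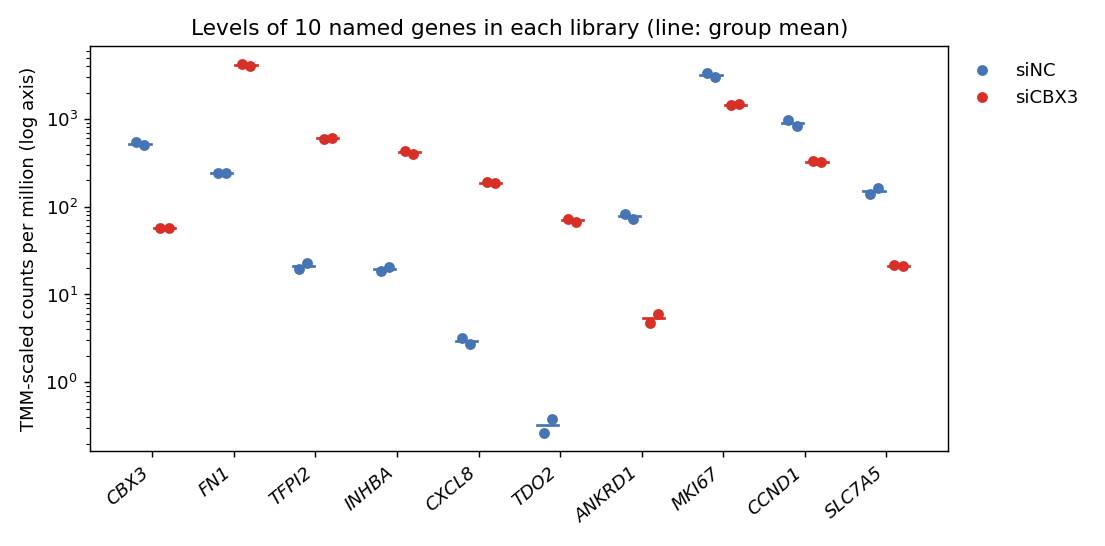
Points give the TMM-scaled CPM of each library (log axis) for 10 named genes, siNC in blue and siCBX3 in red, with lines at group means. In each gene both siCBX3 libraries lie on 1 side of both siNC libraries. The naming rule required this of FN1, TFPI2, INHBA, CXCL8, TDO2 and ANKRD1 as genes taken by size or p-value. FN1 moved from 242 to 4105 CPM and ANKRD1 from 78.1 to 5.36 CPM.

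Inflammatory genes of the NF-kB list rose together. Of 24 tested members 19 rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 1.47. Beside CXCL8, IL6 and PTGS2, the cytokine LIF rose from 3.91 to 123 CPM and the mitochondrial superoxide dismutase SOD2 from 36.9 to 402 CPM. The list was called by camera at the preset correlation (adjusted p 3.0e-08), with adjusted p = 0.604 with an estimated correlation. Interferon response genes moved both ways. In that list 20 of 43 members rose and 8 fell (22 and 9 adjusted over the list alone), with a median of 0.52. The antiviral genes IFIT2 (4.08), IFI44 (3.92), IFIT3 (3.33) and ISG15 (2.44) rose on the log2 scale. PSMB9 (-2.30), USP18 (-1.09) and OAS3 (-0.99), chosen after their values were seen, fell. Camera called the list at the preset correlation (adjusted p 0.0411), but adjusted p = 0.604 with an estimated correlation, and adjusted p was 0.0694 among genes with a mean of at least 50 counts.

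Matrix, adhesion and TGF-beta genes rose as groups. In the list of matrix and mesenchymal genes 29 of 45 members rose and 6 fell (30 and 6 adjusted over the list alone), with a median of 0.67 (camera adjusted p 1.37e-06; adjusted p = 0.604 with an estimated correlation). Collagen genes COL5A1 (2.81) and COL4A1 (2.19) and the collagen-binding SPARC (2.43) rose with FN1. Integrin and adhesion genes rose in 17 of 24 members and fell in 3, the same counts when adjusted over the list alone (16 and 1 without siCBX3 replicate 2), with a median of 0.40. Collagen-binding integrins led it, with ITGA11 at 2.95, ITGA1 at 2.41, ITGA10 at 1.92 and ITGA2 at 1.19 (camera adjusted p 0.000219; adjusted p = 0.604 with an estimated correlation). Of 23 TGF-beta and BMP targets 17 rose and 5 fell, also when adjusted over the list alone, with a median of 0.66 (17 and 3 among genes with a mean of at least 50 counts). PMEPA1, a target and inhibitor of TGF-beta signalling, rose by 3.43, the matrix protein TGFBI by 1.79 and the receptor TGFBR2 by 1.71 (camera adjusted p 0.00145; adjusted p = 0.604 with an estimated correlation). Osteoblast lineage genes rose in 8 of 15 members and fell in 2 (8 and 3 adjusted over the list alone), with a median of 0.40, and the list was not called (camera adjusted p 0.0796), except with limma-voom (0.0237). Without siCBX3 replicate 1, 5 of them rose and 2 fell, with the DESeq2 test 5 and 1, and on RPKM plus 1 3 and 2. SPP1, the gene of osteopontin, rose by 2.82 and TNFRSF11B, the gene of osteoprotegerin, by 3.10. PTH1R, the parathyroid hormone receptor gene, had 0.507 CPM in siNC and 2 and 0 counts in siCBX3.

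Lysosome, autophagy and iron or redox genes also rose. In the autophagy and lysosome list 18 of 27 members rose and 0 fell, also when adjusted over the list alone, with a median of 0.42. The lysosomal protease CTSB rose from 190.2 to 796 CPM, and the autophagy genes GABARAPL1, WIPI1 and SQSTM1 by 2.28, 1.71 and 1.46 (camera adjusted p 6.1e-05; adjusted p = 0.604 with an estimated correlation). The NRF2 and ferroptosis list rose in 16 of 24 members and fell in 3 (17 and 4 adjusted over the list alone, and 10 and 2 on RPKM plus 1), with a median of 0.37. The ferritin chain FTH1 (1.47), ME1 (1.68), ACSL4 (0.94) and the lipid peroxidase GPX4 (0.86) rose (camera adjusted p 0.00262; adjusted p = 0.604 with an estimated correlation). FTH1 shares 62.4% of its exon bases with BEST1 on the opposite strand.

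Genes of cell division and DNA replication fell together. Of 42 mitotic genes 39 fell and 1 rose (40 and 1 adjusted over the list alone), with a median of -0.56. MKI67 (-1.13), the anaphase activator CDC20 (-0.98), the mitotic kinesin KIF20A (-0.90) and the topoisomerase TOP2A (-0.89) fell (camera adjusted p 2.18e-09; adjusted p = 0.604 with an estimated correlation). Of 40 genes of G1/S transition and replication 31 fell and 0 rose (33 and 0 adjusted over the list alone), with a median of -0.54. They included CLSPN (-0.95), MCM10 (-0.93), the thymidylate synthase TYMS (-0.88) and MCM6 (-0.78) (camera adjusted p 2.51e-08; adjusted p = 0.604 with an estimated correlation). Homologous recombination genes fell in 17 of 30 members and rose in 2 (17 and 3 adjusted over the list alone), with a median of -0.39. Examples were RAD51C (-1.01), EXO1 (-0.81), BRCA2 (-0.78) and RBBP8 (-0.61) (camera adjusted p 0.00262; adjusted p = 0.604 with an estimated correlation).

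Most MYC-linked ribosome assembly genes fell. In the ribosome assembly list 26 of 34 members fell and 4 rose (28 and 4 adjusted over the list alone), with a median of -0.36. The polyamine enzymes ODC1 (-1.40) and SRM (-1.27) and the nucleolar proteins FBL (-0.78) and NOP2 (-0.67) fell (camera adjusted p 9.59e-05; adjusted p = 0.604 with an estimated correlation). Ribosomal protein genes rose in 34 of 78 members and fell in 7, also when adjusted over the list alone, with a median of 0.14. The counts were 16 and 10 with library totals, 23 and 9 with upper-quartile scaling, 22 and 4 without siCBX3 replicate 1, 16 and 6 without siCBX3 replicate 2 and 8 and 6 on RPKM plus 1. RPL13A (0.73), RPL11 (0.60), RPS9 (0.58) and RPL3 (0.57) rose (camera adjusted p 0.0188; adjusted p = 0.745 with an estimated correlation). Their call ended without siNC replicate 1 (adjusted p 0.135) or siCBX3 replicate 2 (0.196), with library totals (0.120), among genes with a mean of at least 50 counts (0.0519) and on RPKM plus 1 (0.0790) or plus 0.1 (0.118). YAP targets fell in 15 of 22 members and rose in 1, also when adjusted over the list alone, with a median of -0.57. Beside ANKRD1, AJUBA (-1.47), WWC1 (-1.20) and CYR61 (-1.12) fell (camera adjusted p 0.000297; adjusted p = 0.604 with an estimated correlation).

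**Figure D3:**
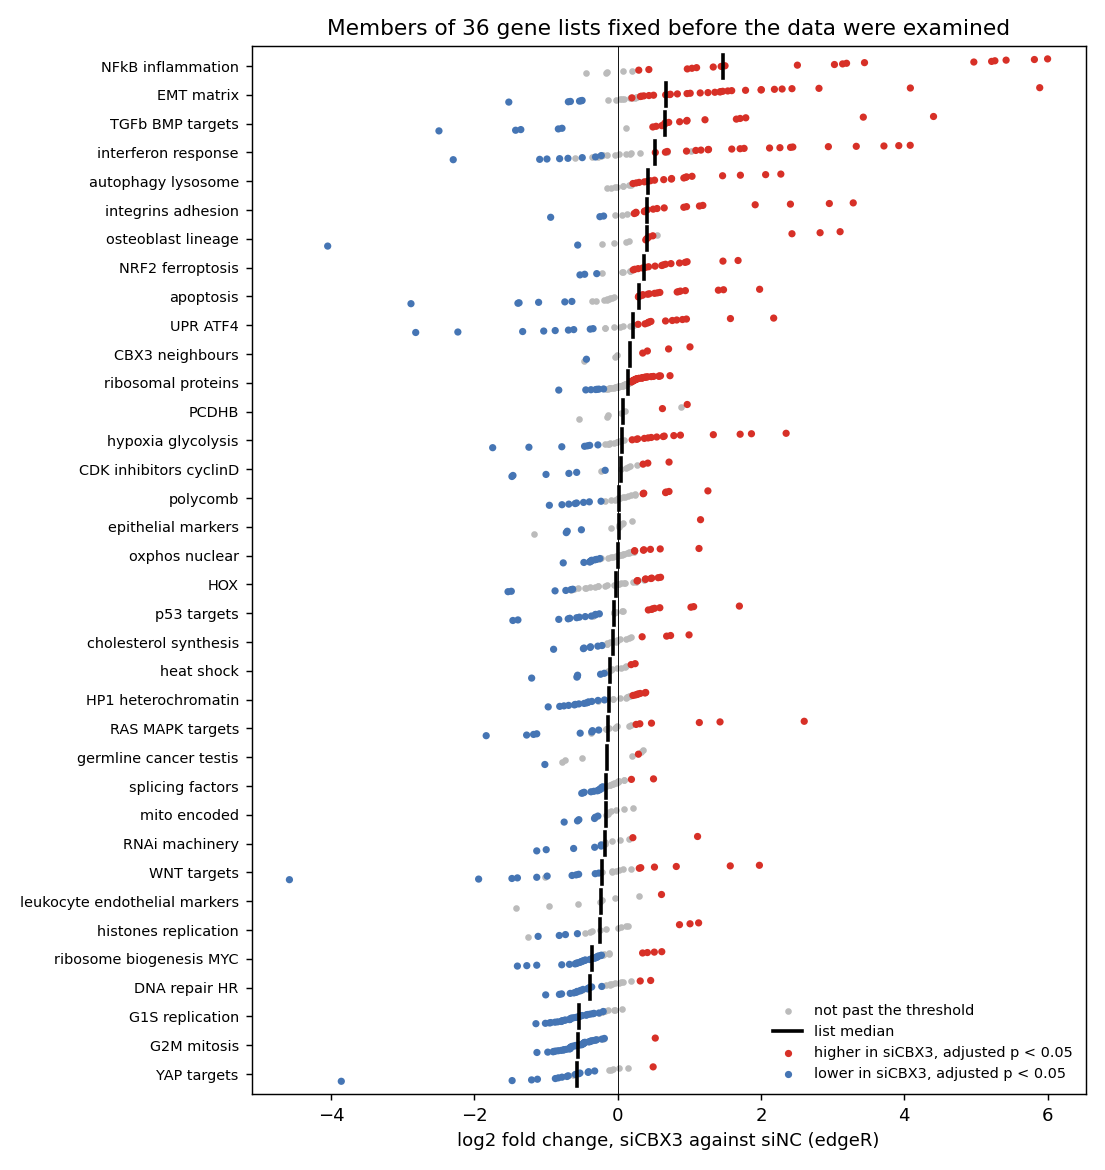
Each point is a tested member of a gene list fixed before the data were examined, at its edgeR log2 fold change of siCBX3 against siNC; black bars mark list medians, and the broad zinc finger lists are left out. The NF-kB list has the highest median (1.47) and the YAP targets the lowest (-0.57).

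The remaining 25 lists were not called at the preset correlation (osteoblast lineage included), with adjusted p between 0.0691 and 0.972. Counts of their members were the same adjusted over the list alone unless given. Heterochromatin partners of HP1 fell in 14 of 30 members and rose in 7, with LBR (-0.97), HELLS (-0.81), UHRF1 (-0.75) and TRIM28 (-0.60) among those that fell. Without siCBX3 replicate 2 the list had 12 falling and 4 rising, and on RPKM plus 1 it had 14 and 2. Polycomb genes rose in 6 of 26 members and fell in 8, with JARID2 at 1.26 and PCGF5 at -0.95, but rose in 8 and fell in 7 without siCBX3 replicate 2. Zinc finger genes rose in 87 of 375 members and fell in 67 (83 and 65 adjusted over the list alone), a balance that turned to 64 and 85 with library totals and to 73 and 78 with upper-quartile scaling. On RPKM plus 1, 38 rose and 54 fell. Those on chromosome 19 rose in 25 of 161 and fell in 25 (21 and 21 adjusted over the list alone), against 18 and 30 with library totals, 21 and 28 with upper-quartile scaling, 18 and 12 with the DESeq2 test and 7 and 20 on RPKM plus 1. In the PCDHB cluster 2 of 8 genes rose and 0 fell (0 and 0 adjusted over the list alone, without siCBX3 replicate 2 and with the DESeq2 test). HOX genes rose in 8 of 36 members and fell in 6 (7 and 6 adjusted over the list alone), against 6 and 9 with library totals and 5 and 10 on RPKM plus 1, and HOXD10 had -1.53. The germline list held 36 genes, of which 24 were among the deposited features and only 8 passed the count filter. Most germline genes were therefore not tested. Of 8 germline genes 1 rose and 1 fell, the latter being TEX15 (-1.02), against 0 and 1 without siNC replicate 1 or with library totals, 1 and 2 without siNC replicate 2 and 2 and 1 without siCBX3 replicate 1. Replication-dependent histone genes rose in 3 of 17 members and fell in 4, against 1 and 4 without siNC replicate 1 or siNC replicate 2, and 1 and 5 without siCBX3 replicate 2.

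Among regulators of growth and survival, CDK inhibitor and cyclin D genes fell in 6 of 15 members and rose in 3 (6 and 1 on RPKM plus 1). The list's median of 0.05 differed in sign from its downward camera test, but it lay between -0.149 and 0.0877 over the alternatives. Cyclin D1, CCND1, fell from 905 ± 105 to 325 ± 4.63 CPM. Targets of p53 rose in 8 of 27 members and fell in 12 (4 and 9 without siCBX3 replicate 1 and on RPKM plus 1, 6 and 7 with the DESeq2 test), with PERP at 1.70 and ZMAT3 at -1.46. Apoptosis genes rose in 17 of 33 members and fell in 6 (17 and 7 adjusted over the list alone, and 11 and 6 on RPKM plus 1), led by the BH3-only genes BMF (1.98) and PMAIP1 (1.48). WNT targets rose in 6 of 25 members and fell in 11, with WNT5A at 1.98 and DKK1 at -1.40. Targets of RAS and MAPK rose in 6 of 24 members and fell in 9 (3 and 9 on RPKM plus 1), with IER3 at 2.60 and EPHA2 at -1.18. Genes of RNA interference rose in 2 of 13 members and fell in 6 (1 and 4 without siCBX3 replicate 1 or siCBX3 replicate 2), with TNRC6C at -1.13. Splicing factor genes fell in 14 of 30 members and rose in 2, with small changes such as TRA2B at -0.50 (7 and 1 without siCBX3 replicate 1, 8 and 1 without siCBX3 replicate 2). That list was called downward in 5 of 16 alternatives, among them library totals (adjusted p 0.0259) and limma-voom (0.0145), over a range of 0.00428 to 0.185.

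Metabolic and stress lists were mixed. Genes of the ATF4 and unfolded protein responses rose in 13 of 31 members and fell in 9 (7 and 8 on RPKM plus 1), with DDIT4 at 2.18 and the amino acid transporter gene SLC7A5 falling from 151 ± 18.1 to 21.3 ± 0.707 CPM. Hypoxia and glycolysis genes rose in 15 of 32 members and fell in 7, where the angiogenic factor VEGFA rose from 147 to 752 CPM and HK2 fell by 1.24 on the log2 scale. Heat shock genes rose in 2 of 16 members and fell in 6 (0 and 8 with library totals, 0 and 4 without siCBX3 replicate 2), and cholesterol synthesis genes rose in 4 of 24 and fell in 7. Nuclear respiratory chain genes rose in 7 of 34 members and fell in 10 (8 and 11 adjusted over the list alone, 4 and 13 with library totals, 6 and 13 with upper-quartile scaling). This list had a downward camera test and a median of 0.01, which lay between -0.0692 and 0.0247 over the alternatives. Mitochondrially encoded protein genes fell in 6 of 13 members and rose in 0, with MT-ND2 at -0.75. Single libraries decided that count: without siNC replicate 1, 4 rose and 4 fell (median 0.01), and without siNC replicate 2, 0 rose and 11 fell and the list was called (adjusted p 0.0312). Without siCBX3 replicate 2, 1 rose and 3 fell, and with the DESeq2 test 0 and 3.

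Neighbours of CBX3 on chromosome 7 rose in 4 of 8 members and fell in 1, or 2 and 1 with library totals, the DESeq2 test or RPKM plus 1, and 3 and 2 without siCBX3 replicate 1. SKAP2 (1.01) and TAX1BP1 (0.71) rose and HNRNPA2B1 fell by 0.44 on the log2 scale, while NFE2L3 had -0.03 (adjusted p 0.752, edgeR). Epithelial markers rose in 1 of 11 members and fell in 3 (0 and 3 with the DESeq2 test), the keratins KRT8 (-0.72) and KRT18 (-0.70) among those that fell. KRT8 and KRT18 share 525 exon bases on opposite strands, so part of their counts can be the same reads. The epithelial list had a downward camera test and a median of 0.01, which lay between -0.313 and 0.0285 over the alternatives. Of 8 measured leukocyte and endothelial markers 1 rose and 0 fell (2 and 0 without siCBX3 replicate 1), and only 3 were above 1 CPM in siNC. The riser was CD68, from 413 to 626 CPM, which shares 81.7% of its exon bases with RP11-186B7.4. PTPRC stood at 0.381 CPM in siNC and 0.195 CPM in siCBX3.

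Signs of library composition moved with the groups. The mitochondrial rRNA share was 0.98% and 0.78% of counts in siNC and 1.76% and 1.61% in siCBX3, while the share of all mitochondrial genes (9.8% and 8.04% against 9.33% and 7.96%) overlapped between groups. The nuclear RNA MALAT1 made up 0.029% and 0.038% of counts in siNC and 0.142% and 0.159% in siCBX3. Coding genes held 93.53% and 93.65% of counts in siNC and 92.31% and 92.39% in siCBX3. Of the genes named by the rule, CCND1, SLC7A5, WWC1 and DKK1 carried the 7-mer GACGTGT in the longest 3' UTR. Genes with this sequence were lower on average in siCBX3, where 51.2% of those with only the 7-mer fell and 19.9% rose. Among genes with neither the 7-mer nor its 6-mer ACGTGT, 28.5% fell and 30.8% rose. Of the 12 largest falls 0 were found to carry it, where CYP46A1, MEST and SLC7A3 were among those not searched. No second siRNA against CBX3 or rescue was analysed here, so the values describe 1 siCBX3 arm.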

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

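Offsets for GC content and gene length, and the count without genes that hold the 3' UTR 7-mer, were chosen after seeing the data. The CBX3 log2 fold change stayed negative in every alternative, between -3.15 and -3.23 with each library left out in turn. The count of genes changed, siCBX3 against siNC, was 10173 and lay between 8341 and 9654 (4232 to 5013 higher, 4109 to 4641 lower) with single libraries left out, where the lone library is assumed to vary like the other group. Limits on size cut it most: glmTreat at 1.5-fold gave 2720 (1467 higher, 1253 lower) and an absolute log2 fold change of at least 1 gave 2696 (1347 higher, 1349 lower). DESeq2 called 8276, limma-voom 10172, RPKM plus 1 8597, the GC and length offsets 10079, and 9951 were left without genes holding the 7-mer. No called gene was called in the other direction, but the balance of 5132 higher and 5041 lower turned to 4243 and 5917 with library totals (41.8% higher, against 50.4%), 4657 and 5626 with upper-quartile scaling, 4609 and 5470 with the offsets, 3584 and 5013 on RPKM plus 1 and 3606 and 5036 on RPKM plus 0.1. Of the 13 lists called at the preset correlation, camera with an estimated correlation called 0 (1 list, the NF-kB list, at unadjusted p 0.0374) while fry called 12 of the 13 (21 of all 38). Single-library omissions gave 12 to 14 called lists. Interferon and ribosomal protein genes lost their call in some alternatives, and splicing factor, osteoblast and mitochondrially encoded genes gained one in some; the cause was not tested. Of 167 named genes past the threshold 160 passed in every alternative run without a limit on size. The replicate block gave 10630 changed genes. Deviations of same-numbered libraries correlated only weakly, at 0.0287 over all genes and 0.0849 over genes above a log2 CPM of 3. The mitochondrial share was higher in replicate 1 of both groups (9.8% against 8.04% in siNC, 9.33% against 7.96% in siCBX3). A small effect shared by same-numbered libraries is therefore not excluded. Small changes may be missed, but the simulation does not measure how many. It changed 200 of 20560 genes at these depths and recovered 11 of 50 at the smallest fold, whereas 10173 genes were called in the data. The adjusted threshold is stricter when few genes change, so that share does not carry over. Scaling with a large share of genes changed was not simulated, and neither depth nor library number was varied.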

Other observations

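The gene families below, the 7-mer scan and every test in the paragraphs after them were chosen after the results were seen, except that 4 tests had a written prediction first: the 7-mer in CBX3 transcripts, the 7-mer in POLE3 and C9orf43, their shared exon bases, and the siNC-side 7-mer. The wording of those predictions was revised once, after the results of the first 3 had been seen. Families were formed from the letters of gene symbols, and 10 of 242 were called by camera at the preset correlation (0 with an estimated correlation, adjusted p = 0.938). Collagen genes (COL) rose in 24 of 38 members and fell in 6, with a median log2 fold change of 0.66, and matrix metalloproteinase genes (MMP) rose in 10 of 16 and fell in 0, with a median of 0.74. Among serpins of clade B (SERPINB) 4 of 8 genes rose and 0 fell. Non-clustered protocadherin genes (PCDH) fell in 8 of 8 members, with a median of -1.90. The clustered PCDHA genes fell in 10 of 13 members and the PCDHGA genes rose in 12 of 12, but the total counts of PCDHA genes lay between 187 and 193 and shared last exons make each cluster 1 measurement. Nuclear pore genes (NUP) fell in 13 of 21 members and rose in 1, mitochondrial ribosome genes (MRPL) fell in 23 of 49 and rose in 3, RAD genes fell in 12 of 20 and rose in 2, and MCM genes fell in 8 of 10 and rose in 0.

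Non-coding genes changed too. MALAT1 rose from 325 to 1545 CPM, and 2 short segments annotated within NEAT1, NEAT1_1 and NEAT1_2, rose by 1.58 and 1.76 on the log2 scale. MIR3142HG, a microRNA host gene, rose from 1.45 to 19.1 CPM, LUCAT1 by 2.46 and DNM3OS by 3.68. Small nucleolar RNA genes fell in 17 of 91 members and rose in 2, with SNORD86 at -1.67 and SNORD57 at -1.26. Of all 20999 tested genes 5041 fell and 5132 rose, so the share that fell was no higher here, and the share that rose was lower. Their median was -0.36 (camera adjusted p 0.0175 at the preset correlation, adjusted p = 0.750 with an estimated correlation). Most such genes lie inside host genes. The mitochondrial rRNA MT-RNR2 rose by 1.03, whereas MT-RNR1 had -0.17 (adjusted p 0.0671, edgeR). KYNU, which acts after TDO2 in tryptophan breakdown, had 4 and 4 counts in siNC and 104 and 162 in siCBX3. The pseudogene CBX3P9 had 26 and 46 counts in siNC and 2 and 0 in siCBX3; as a copy of CBX3 it is treated as uncertain, and how reads were divided between them was not tested.

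Genes whose 3' UTR holds GACGTGT, 315 of 12013 searched genes, were lower on average in siCBX3. Their mean shift was -0.36 on the log2 scale, with t = -10.15, beyond the lowest t of -4.92 in 100 shuffles. Of those with the 8-mer GACGTGTA 50.8% fell and 16.9% rose. Of those with only the 7-mer 51.2% fell and 19.9% rose, and the rest of either group were not called. Among genes with none of these sites and without the 6-mer ACGTGT, 28.5% fell and 30.8% rose. The 7-mer ranked first both on odd-numbered chromosomes (t = -7.22) and on the others (t = -7.07). Base composition is argued against, since the lowest t of the 419 other 7-mers made of the same bases was -4.5 (SD 1.15), and UTR length was a term of the regression. A candidate explanation is off-target silencing through the seed of the siCBX3 duplex: 100% of the 3 coding transcripts of CBX3 hold the 7-mer, as GACGTGTA in exon 3 (chromosome 7, 26206456 to 26206463), against 6.64% of all coding transcripts. The 3 transcripts share this site, at base 113 from the start codon, so it is a single site in a single gene. The predicted order of site strength held only in part, since genes with the 8-mer had a median of -0.28, those with the 7-mer -0.29 and those with the 6-mer ACGTGT -0.04, and genes with the 7-mer in the coding part (655) or the 5' UTR (120) were lower by 0.13 and 0.18. The siRNA sequence is not given in the sources used here, an effect of CBX3 loss on these genes was not tested, and the 7-mer lies in 161 of the 3566 searched genes that fell (4.52%) and in 46 of the 470 that fell 2-fold or more (9.79%).

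POLE3 and C9orf43, head-to-head genes on chromosome 9, fell together, from 228 to 46.4 CPM and from 42.8 to 9.53 CPM. Seed-based silencing of both is argued against, since only 1 of them, POLE3, holds the 7-mer in its 3' UTR (as the 8-mer), and 0 of 2 annotated coding transcripts of C9orf43 hold it in any part. Reads of POLE3 counted for C9orf43 remain open: the exons share 104 bases of the 2290 in C9orf43, and how many C9orf43 reads fall there was not measured. The fall of C9orf43 was not explained by these values, and no biological explanation was tested.

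The rise of NF-kB and interferon genes may reflect loss of CBX3, which the design names and which was not tested against other causes. Leukocytes or endothelial cells in the cultures stay open: their 8 markers had a median log2 fold change of -0.23 (SD 0.66) against 1.47 for the NF-kB list, but only 3 were over 1 CPM in siNC, and the abundant CD68, which rose by 0.60, shares most of its exon bases with another gene. Release from silencing by the siNC duplex was predicted to put the 7-mer with the highest t in over 50% of the risen members, and 17.6% of the 34 searched ones held it (exact 95% interval 6.76 to 34.5%). That prediction was ill-posed, because this 7-mer's t of 4.83 lay under the 5.31 that shuffles reached and so names no siNC seed. A response to the siCBX3 duplex other than CBX3 loss cannot be told apart from it, because there is 1 siCBX3 arm.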
